A study of Homo sapiens with 5 samples.

How the data were processed

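H3K27ac was measured by chromatin immunoprecipitation with a rabbit antibody and sequencing of single-end reads in 5 primary Wilms tumours, per the labels. The 5 samples form 1 group, and each was treated as a separate tumour as the labels present them; the labels do not state that they came from separate patients, so the spread and the p-values describe these samples. Replicate numbers only name the tumours.

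The submitters' processing notes name Trim Galore 0.4.1, Bowtie2 2.3.2, Picard, MACS2 2.1.1, deepTools and the build hg19, without their roles or settings. Whether an input library entered the peak calling is not given in the sources used here. The authors deposited 1 list of broad peaks per sample, so peaks were called per tumour. Each deposited peak has a start and end, a fold enrichment (a ratio), a −log10 p-value, a −log10 q-value and a score. Per the values in the deposited files, the score equals 10 times the −log10 q, rounded down, in at least 99.992% of peaks of each list, and it was not used further. The smallest deposited −log10 q was 1.01 ± 0.00219 (SD, n = 5). In each list the smallest gap between peaks was 4 times the narrowest peak plus 1 bp, with a mean of 900 bp, so that closer peaks appear as 1. Fold and −log10 q are each list's own values and were used only to describe, rank or filter peaks within that list. The lists hold no read counts, so depth is unknown and no counting interval or floor is given. No pair of lists had more than 4 autosomal peaks with the same start and end, so no library was treated as deposited more than once.

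Values per tumour used chromosomes 1 to 22, which held 97.1% of the 677738 peaks. Bases covered by peaks of 1 to 5 tumours were counted, and overlapping peaks were merged into regions; an overlap of 1 bp counted as shared. The bases marked in all 5 were tested one-sided against 100 placements of each list at random positions of the same chromosome, without overlap and with a fixed seed; the end of the last peak served as the chromosome's length. Similarity of a pair was the Jaccard index. Recurrence was the percent of a tumour's peaks that overlap a peak in all other 4, by deciles of −log10 q or width, with an exact two-sided sign-flip permutation test over 5 differences. For domains, peaks within 12500 bp were stitched, ranked by the sum of fold times width, and the top 500 of each tumour were compared. Calculations used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures matplotlib 3.10.9.

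The regions named by rule are the 10 in the top 500 of all 5 tumours with the best median rank. This rule was set before the data were examined, for the case that no hg19 annotation was used. Other regions named in the text were chosen after their values were seen. The gene table used here is on GRCh38, another build, so peaks were not assigned to genes. The planned results on promoters, on promoter against distal peaks and on gene lists, and the alternative that leaves out peaks near transcription start sites, were therefore not run. Recurrence by strength and width, the shifts of whole lists and the counts of strong peaks seen in 1 tumour were added after the data were examined.

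The interval counts were tested on simulated data. They equalled a base-by-base count in 20 of 20 draws. With 5 independent lists, 0 of 20 draws gave a p under 0.05. These lists came from the same random placement as the test, with 20 placements per draw rather than 100, so clustered lists were not tried. With 2002 planted shared intervals of 2.00 Mb in all, the bases found in all 5 lists came to 100.1% of the planted length. The alternatives were a −log10 q of at least 5, a fold of at least 4, the same number of peaks from each tumour (115908, highest −log10 p first), each tumour left out, 50% overlap, the top 250 or 1000 domains, stitching within 5 kb or none, and ranking by width. Placement outside stretches without peaks, and domains without the peaks near them, were added later.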

Results

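Acetylation of histone H3 at lysine 27 (H3K27ac), a chromatin mark found at active promoters and enhancers, was profiled by chromatin immunoprecipitation and sequencing in 5 primary Wilms tumours. Wilms tumour is a childhood cancer of the kidney. The 5 tumours formed 1 group without a control group, so the comparisons were between tumours: how much marked chromatin they had in common, how similar each pair was, which peaks recurred, and which regions carried the most of the mark. The data were 1 list of broad peaks per tumour in hg19 coordinates. These lists hold no read counts, so the sequencing depth behind each peak is unknown. Values per tumour are for chromosomes 1 to 22.

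H3K27ac peaks covered 154 ± 23.2 Mb of the autosomes per tumour (mean ± SD, n = 5), with a range from 124 to 180 Mb. The number of autosomal peaks was 131648 ± 12744 (SD, n = 5) and ranged from 115908 in tumour 2 to 145067 in tumour 4. The median peak was 988 ± 89.7 bp wide (SD, n = 5), and the median fold enrichment, as the authors deposited it, was 2.24 ± 0.0748 (SD, n = 5). Tumour 1 had 57094 peaks with a −log10 q of at least 5 and tumour 3 had 20572, a count that also depends on the unknown depth.

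A core of bases lay under H3K27ac peaks in every tumour. Of the 363 Mb marked in at least 1 tumour, 38.6 Mb (10.6%) were marked in all 5, 31.8 Mb in exactly 4, 43.6 Mb in 3, 70.3 Mb in 2 and 179 Mb (49.2%) in 1 only. After merging of overlapping peaks, 44108 of 263022 regions (16.8%) held a peak from all 5 tumours. These regions had a median width of 2292 bp, against 608 bp for the 111163 regions found in 1 tumour, a difference that arises in part by construction, since a merged region spans all of its peaks. Random placement of each list on its own chromosomes put 0.00197 ± 0.000947 Mb in all 5 (SD over 100 placements), and none of the 100 reached the observed value (one-sided permutation p = 0.0099, n = 5, the smallest that 100 placements can give). When whole lists were moved by 0.1 to 1 Mb, which keeps the clustering of peaks, 0.0123 ± 0.00221 Mb fell in all 5 (permutation p = 0.0099, again the smallest possible). Both tests ask only whether the lists overlap more than displaced lists would. Without another tissue they cannot tell whether the shared bases are particular to these tumours. Nor can they separate acetylation from peaks that recur at fixed places for other reasons.

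**Figure D1:**
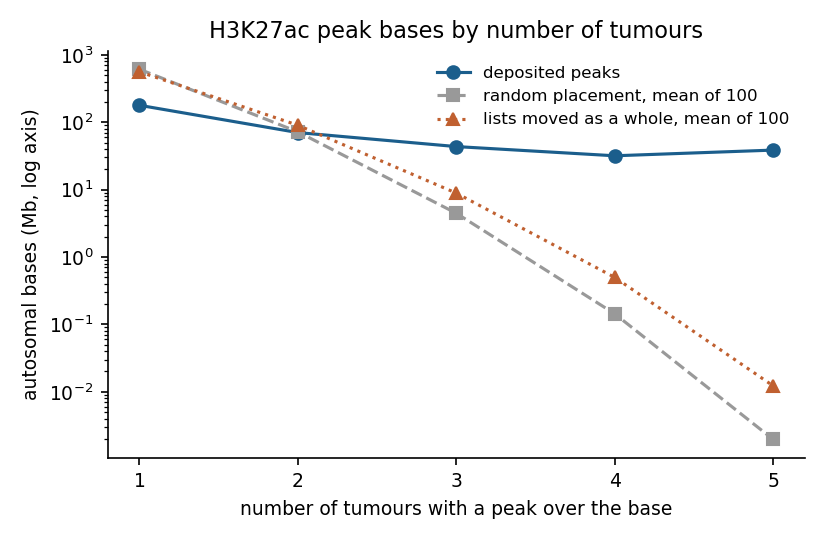
Autosomal bases in Mb (log axis) covered by peaks of exactly 1 to 5 tumours, for the deposited lists, for the mean of 100 random placements and for the mean of 100 shifts of whole lists. The deposited lists share 38.6 Mb among all 5 tumours, against 0.00197 Mb and 0.0123 Mb.

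The shared bases were spread unevenly over the chromosomes. Outside stretches of 1 Mb or more without a peak in any tumour, they made up 1.43% of the autosomes. Chromosome 19 had the highest density, with 3.35% of its length marked in all 5 tumours, followed by chromosome 17 with 2.90% and chromosome 22 with 2.82%. Chromosome 4 had the lowest, 0.643%, and chromosome 13 the next, 0.917%. On chromosome 19, 17.6% of all bases marked in any tumour were marked in all 5, against 7.75% on chromosome 4. These densities describe the 5 tumours together and were not tested.

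In the lists as deposited, tumours 4 and 5 were the most alike, and tumour 2 stood lowest in similarity. The Jaccard index (shared bases over the union of bases) was 0.445 for tumours 4 and 5. All 4 pairs with tumour 2 lay between 0.281 and 0.294, and the other pairs between 0.320 and 0.379. The mean of each tumour with the others was 0.338 ± 0.0318 (SD, n = 5). Among the 29313 regions present in exactly 4 tumours, tumour 2 was the missing one in 13686 (46.7%), tumour 3 in 5664, tumour 1 in 3565, tumour 5 in 3487 and tumour 4 in 2911. With an equal number of peaks from each tumour, tumour 2 stayed lowest, with a mean index of 0.291. Tumours 4 and 5 stayed highest there, with 0.461. The positions did depend on the strength of the peaks that entered. With a −log10 q of at least 5 the mean index of tumour 2 was 0.328, against 0.323 for tumour 1, and with a fold of at least 4 it was 0.409, against 0.362 for tumour 4, then the lowest. Tumours 4 and 5 kept the highest index with a −log10 q of at least 5 (0.495), but with a fold of at least 4 theirs was 0.381 and that of tumours 1 and 5 the highest, 0.475. Pairs share tumours and were not tested.

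**Figure D2:**
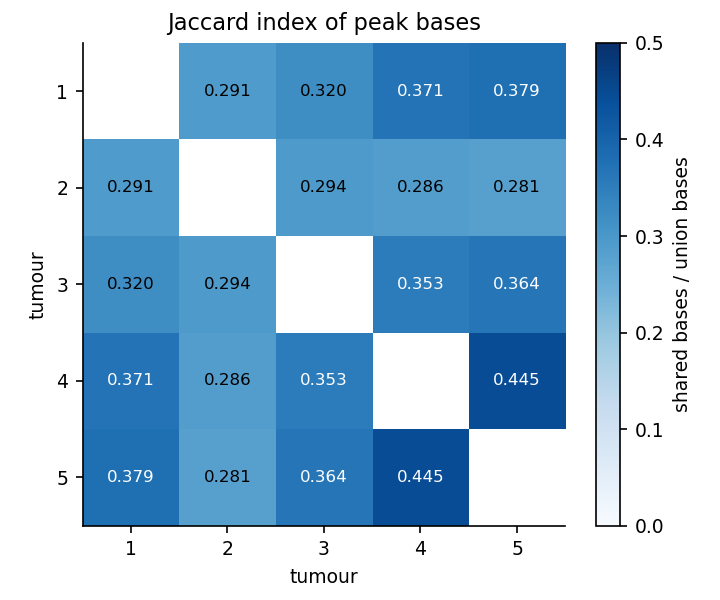
Jaccard index of autosomal peak bases for each pair of the 5 tumours, as colour and number. In the lists as deposited tumours 4 and 5 have the highest index, 0.445, and the 4 pairs with tumour 2 lie between 0.281 and 0.294.

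Peaks with a high −log10 q recurred most often in the other tumours, and in the full lists wide peaks also recurred more often than narrow ones. In each tumour 33.0 ± 3.05% of peaks overlapped a peak in all other 4 (SD, n = 5), and 17.0 ± 4.50% overlapped none. In the decile of each list with the highest −log10 q, 93.0 ± 3.51% recurred in all other tumours, against 7.14 ± 3.11% in the lowest decile (SD, n = 5). The difference of 85.9 ± 2.49 percentage points had the same sign in 5 of 5 tumours (exact two-sided sign-flip permutation p = 0.063, the smallest that 5 tumours allow, so p under 0.05 was out of reach). The widest decile recurred in 64.9 ± 3.14% and the narrowest in 7.61 ± 2.80%, a difference of 57.3 ± 3.72 points (SD, n = 5; exact permutation p = 0.063). Each tumour's recurrence was counted against the other 4 lists, so the 5 differences are not independent. The p-values for recurrence therefore describe these lists and do not measure replication over separate tumours. The difference by width was 1.95 ± 17.4 points among peaks with a fold of at least 4 (exact permutation p = 0.875, n = 5), 30.4 with a −log10 q of at least 5, and 26.5 when 50% of a peak had to be covered. Wide peaks also have more chance to meet a peak of another list, which bears on both comparisons. The decile with the highest −log10 q had a median width of 1627.5 ± 125 bp, against 624.5 ± 29.9 bp in the lowest (SD, n = 5). The lowest decile had a median −log10 q of 1.21 to 1.43, near the smallest deposited value, so its counterparts may be unlisted.

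**Figure D3:**
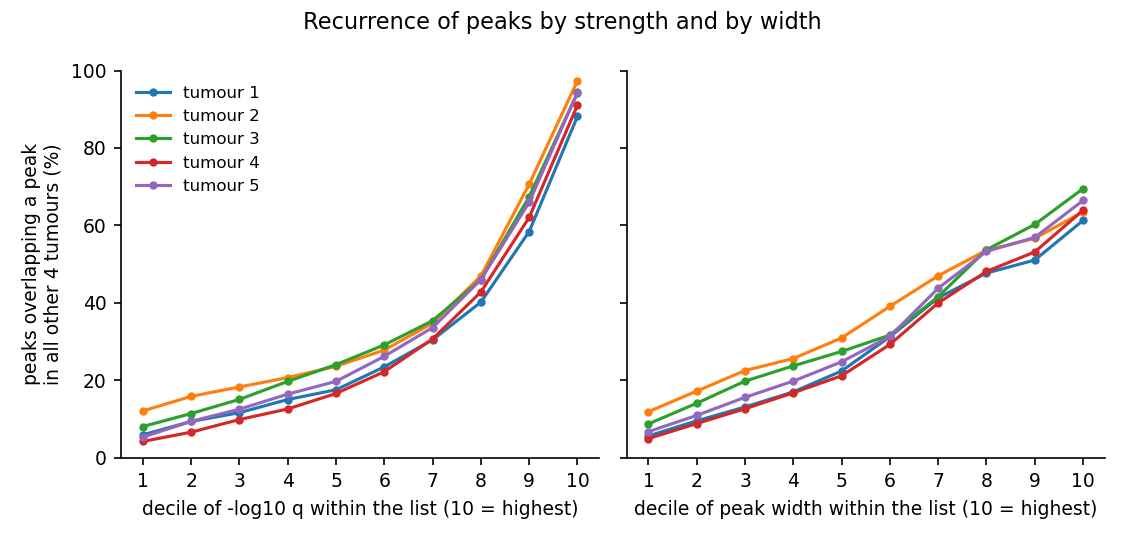
Percent of autosomal peaks that overlap a peak in all other 4 tumours, by decile of −log10 q (left) and of width (right) within each list, with 1 line per tumour. The mean rises from 7.14% to 93.0% with −log10 q and from 7.61% to 64.9% with width.

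Some of the largest domains of peaks were common to all tumours. Neighbouring peaks were stitched into domains, and the 500 domains with the highest sum of fold times width were taken from each tumour. Domains that overlapped between tumours were merged, which gave 1221 regions. Of these, 59 (4.83%) were in the top 500 of all 5 tumours and 642 (52.6%) of 1 only. A tumour's rank in a region is that of its best domain there. The bases given as covered count all of its peaks in the merged span. A top domain had a median length of 179 ± 29.9 kb and 28.2 ± 5.89 peaks, and the 500 held 13.7 ± 1.59% of the peak bases of a list (SD, n = 5). A domain just below the top 500 of a list counted as absent from it, so these shares depend on that limit: with the top 1000 the count in all 5 was 201, and with the top 250 it was 18. It was 31 with stitching within 5 kb and 19 without stitching.

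The region with the best median rank, 6, was on chromosome 16 from 84940795 to 85708354. It ranked between 2 and 148 in the 5 lists, and peaks covered 150 ± 25.2 kb of it (SD, n = 5), of which 48.6 kb were common to all tumours. Next came chromosome 1 from 144811497 to 145596844, with a median rank of 17 and 152 ± 14.2 kb covered, and chromosome 13 from 98759804 to 99249363, with a median rank of 25 and 103 ± 19.7 kb covered. A region on chromosome 2 from 238026096 to 238669334 had a median rank of 29, ranging from 3 to 348. The region on chromosome 6 from 43589123 to 44250348 had a median rank of 39, and that on chromosome 19 from 679597 to 1525423 a median rank of 42. Median ranks were 50 for chromosome 9 from 130426567 to 131103827, 53 for chromosome 16 from 1907142 to 2302414, 55 for chromosome 7 from 444868 to 1716410 and 57 for chromosome 12 from 124353524 to 125498961. The bases common to all tumours came to 69.8 kb in the chromosome 7 region and 72.1 kb in the chromosome 12 region, the most among the 10. These were also the longest of the 10, at 1272 and 1145 kb, and for their length they held the least in common. Both exceed the longest top domain of any list, 914 kb, so each joins several overlapping domains and is not a single domain. With peaks of a −log10 q of at least 5, 5 of these 10 regions overlapped a top domain in all 5 tumours; with a fold of at least 4, or without stitching, 0 of 10 did.

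**Figure D4:**
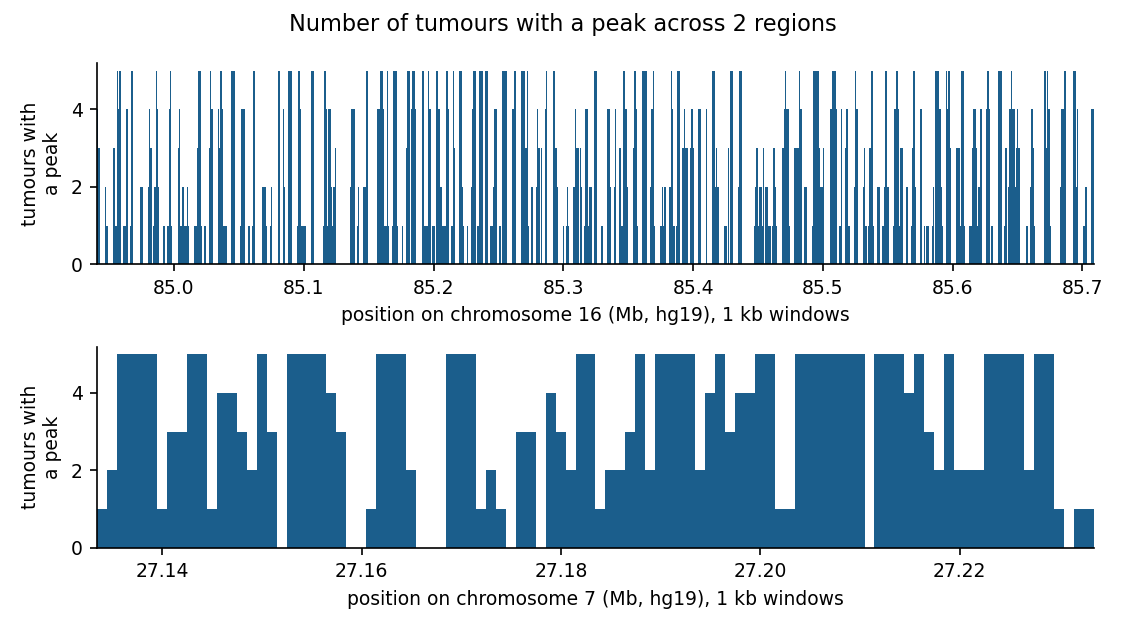
Number of tumours with a peak in each 1 kb window of the chromosome 16 region from 84940795 to 85708354 (top) and of a chromosome 7 region from 27133468 to 27232961 (bottom), hg19. All 5 tumours have a peak in 15.4% of the windows of the first region and in 45% of those of the second.

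Stitching within 5 kb brought forward shorter, densely marked regions, which were singled out after their values were seen. The first, on chromosome 7 from 27133468 to 27232961, ranked between 1 and 59 in the 5 lists with a median of 1. Peaks covered 43.8 ± 13.6 kb of its 99.5 kb (SD, n = 5), and 24.6 kb were common to all tumours. A region on chromosome 2 from 176944016 to 177006186 had a median rank of 16, with 23.1 ± 4.69 kb covered, and one on chromosome 7 from 1258322 to 1300783 a median rank of 42, with 15.5 ± 3.42 kb covered. Of the 10 regions with the best median rank, 7 lay within 1 Mb of a stretch without peaks. These 7 had median ranks of 4 to 13, ahead of the chromosome 2 region, and are not named here. The regions named are those of the 10 that lay away from such stretches. With this stitching, 31 regions were among the top domains of all 5 tumours, and 17 of the 31 lay within 1 Mb of such a stretch.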

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

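All tests in this part were chosen after the results were seen. The 2 values per tumour that stood apart came from 26 measures examined by Dixon's ratio (critical value 0.71 for 5 tumours), and chance alone gives about 1 in 20.

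Tumour 1 stood apart in strong peaks of its own: 2.1% of the strongest decile of its peaks (301 of 14359) overlapped no peak in another tumour, against at most 0.195% in the other 4. In the strongest decile of tumours 2 to 5 the counts were 11, 24, 18 and 9. A −log10 q of at least 20 took 14406 peaks of tumour 1, nearly the same set, of which 302 overlapped no peak in another tumour. In tumours 2 to 5 that cut was stricter and took 7879, 4629, 7784 and 10950 peaks, with 1, 2, 7 and 5 such peaks. These counts therefore add no separate support. A longer list is argued against, since tumour 4 had more peaks (145067, against 143594 in tumour 1) and a share of 0.124%. With an equal number of peaks the share of tumour 1 was 1.98%, and the highest of the others 0.216%. That cut removed only weak peaks, so it could hardly have changed the share. Extra copies of up to 5 chromosomes are argued against as the whole cause, since without the 5 autosomes with the largest excess the share was 1.71%, and the highest of the others 0.194%; gains of more chromosomes were not tested. Too few peaks called in the other tumours is not settled: their lists missed 6.18 ± 2.09% of tumour 1's strongest decile (SD, 4 lists), and in 4 of 4 lists more than of any other tumour (9.13% against at most 6.80% in list 2, 5.93% against 1.77% in list 3, 4.25% against 1.18% in list 4, 5.40% against 1.34% in list 5), which argues against lists that miss all tumours' peaks alike. The 301 peaks in no other tumour are missing from all 4 lists at once, so these are not 4 separate supports. Only list 2 missed more of tumour 1's peaks than the highest value for any pair among tumours 2 to 5, 6.80%. The criterion written for this test asked that of every list. The explanation also stays open because −log10 q grows with depth, which is unknown. With every list cut to a fold of at least 4, tumour 1 had 1.06% against 10.2% in tumour 3. A counterpart with a lower fold then counted as absent, so these values do not decide the question. No biological explanation was tested.

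Tumour 3 stood apart in where its strongest compact domains lay: 38% of its 100 strongest domains with 5 kb stitching were within 1 Mb of a stretch of at least 1 Mb without peaks in any tumour. Over all 5 tumours this was 18.6 ± 11.2% (SD, n = 5), against 1.47 ± 0.296% of all peaks, and it was higher in 5 of 5 (exact permutation p = 0.063, the smallest possible). With a −log10 q of at least 5 the percent was 11.8 ± 4.66 (SD, n = 5), still above the 1.47% of all peaks. Chaining of peaks below that −log10 q is therefore argued against as the whole cause. That comparison was with all peaks, not with the peaks of that −log10 q alone. The stronger peaks were still stitched within 5 kb there, so an effect of the stitching itself was not removed. Tumour 3 fell to 19% and no longer stood apart (Dixon's ratio 0.455, from 0.724). Sequence copies missing from the reference beside such stretches remain a candidate explanation for the 18.6%, and no value here separates them from true acetylation of these places. No biological explanation was tested.

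Peaks also lay outside the chromosomes compared. The mitochondrial genome, which carries no histones, had 3.8 ± 0.837 peaks per tumour, with a median fold of 1.48 ± 0.107 (SD, n = 5). They covered 10.8 to 13.2 kb, and the highest −log10 q was 8.27 to 12.7, so peaks on a genome without histones passed the stricter −log10 q of at least 5 in 5 of 5 tumours. Alternate haplotype contigs held 3029 peaks over the 5 tumours together, and unplaced and unlocalised contigs 2839.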

How the results depend on the processing

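Most alternatives were set before the data were examined; those for recurrence by strength or width and for the strong peaks of tumour 1 were chosen afterwards. Bases marked in every tumour that was kept stayed above random placement under all 10 alternatives run. Placement gave a mean of at most 0.0366 Mb there, so this comparison could hardly have failed. With all 5 tumours the bases came to 2.20 Mb (fold of at least 4) to 38.6 Mb. With a tumour left out they were counted in the remaining 4 and came to 41.2 to 51.8 Mb (without tumour 2). Regions in all 5 fell from 44108 to 13720 with a −log10 q of at least 5 and to 1971 with a fold of at least 4, as fewer peaks entered. The percent of peaks with a counterpart in all others was 40.8 and 39.7 under those settings, 21.9 with 50% overlap, and 35.7 to 42.6 with a tumour left out, where fewer lists must match. The mean Jaccard index was 0.404 with a fold of at least 4, and 0.319 to 0.372 with a tumour left out, highest without tumour 2. The count of top domains in all 5 was 18 for the top 250, 201 for the top 1000, 31 with 5 kb stitching and 19 without stitching. The other settings with all 5 tumours gave 49 to 67. With a tumour left out, the count in the remaining 4 was 67 to 88. The strongest decile recurred more than the weakest under all settings, by 59.9 to 89.8 points. The share of tumour 1's strongest peaks in no other tumour was 1.06% with every list cut to a fold of at least 4 and 4.78% with 50% overlap. Apart from the counts that fewer peaks, lists or domains lower or raise by construction, the cause was not tested. Settings that need gene positions were not run. No paired analysis was possible because there is 1 group. Depth is unknown, so its effect on weak peaks could not be measured.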

Other observations

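The tests in this part were chosen after the results were seen. Some peaks with a high product of fold and width lay at the same place in every tumour. Ranked by that product without stitching, 19 regions were in the top 500 of all 5 lists, and 4 of them lay within 1 Mb of a stretch without peaks, among them the one with the best median rank, 2, on chromosome 1 from 121351756 to 121360263. Away from such stretches, on chromosome 17 from 79313419 to 79320893 peaks covered 7.23 ± 0.149 kb (SD, n = 5), of which 7.07 kb were common to all tumours. On chromosome 15 from 75742779 to 75748689 they covered 5.83 ± 0.0445 kb, with 5.71 kb in common, and on chromosome 13 from 111363536 to 111368762 they covered 5.12 ± 0.0717 kb, with 4.92 kb in common. These regions were chosen after their values were seen, and others away from such stretches agreed less. On chromosome 18 from 106067 to 113442, with a median rank of 38, peaks covered 5.96 ± 0.674 kb (SD, n = 5), with 4.63 kb in common.

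A few of the highest-fold peaks sat at the same places in all 5 tumours. Among the 50 highest-fold peaks of each list, 6 regions were common to all 5 and most were not, and the 6 included chromosome 1 from 91852648 to 91853214 with a fold of 10.1 ± 1.12 and chromosome 12 from 133841335 to 133842060 with 10.1 ± 1.10 (SD, n = 5). The starts of the 6 varied between tumours by a median SD of 11.5 bp (4.66 to 24.2), against 41.9 bp for 261 other narrow shared peaks, and the ends by 22.6 bp (4.83 to 143), against 44.8 bp (one-sided permutation p = 0.00081 and 0.0206). The 261 had a fold of at least 4 and a width under 1200 bp in all 5 lists, but were not matched to the 6 on either. The 6 were narrower, with a median width of 749 bp against 953 bp, so the p-values cannot separate collapsed copies from peak shape. Sequence copies collapsed into 1 reference position may give more fixed edges, and the 11.5 bp goes in that direction, but the ends of 1 region varied by 143 bp and a sharply bounded acetylated element is not excluded. A mean over a narrow peak also tends to be higher, and no biological explanation was tested.

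A few peaks combined a fold under 1.2 with a −log10 q of at least 20. There were 13 of them in 3 tumours, and 6 overlapped no peak in another tumour.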
